A study of Caenorhabditis elegans with 4 samples.

How the data were processed

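Whole worms were grown from hatched larvae to young adults and frozen, RNA was extracted with Trizol, and libraries were made with the ScriptSeq v2 kit, per the labels' protocols. The authors deposited a table of raw counts per gene for the 4 libraries. The aligner, counting tool, genome build, annotation and use of strand are not given in the sources used here, so overlapping genes are named as uncertain. The deposited log2 values are the same counts on another scale: they equal log2 of the count scaled to a common library total, plus 8, with a largest gap of 0.00052 and a minimum of 3 in every library. Fold changes of low genes are therefore compressed on the authors' log2 scale, and tests here used the counts. Groups were taken from the strain label, with 2 libraries each. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which can be technical. Counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 30.3 in wild type and 8.96 in the mutant), so no library was a copy of another.

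Gene IDs were matched to a name table (18778 by ID and 3 by locus tag), 1401 had no symbol (1.34 to 1.6% of the counts) and 19516 had a position in the Ensembl annotation of WBcel235. The 3 symbols reached by locus tag, pat-10, eps-8 and pmt-1, have another row of their own. Both rows of pat-10 are therefore in the muscle list, and both rows of pmt-1 in the fat and lipid list. Exon length is the summed length of merged exons in that annotation, available for 97.5% of tested genes. A genome sequence was not used here, so GC content and sequence similarity between copies were not checked.

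Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test after TMM scaling and its default expression filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of F. The TMM factors ran from 0.985 to 1.01, and the biological coefficient of variation was 0.086. Of 28 gene lists fixed before the data were examined, 27 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The list of mitochondrially encoded genes had 0 members among the genes of the table used here. DESeq2 1.42.0, limma on the deposited log2 values, fry and camera with an estimated correlation were alternatives, as were other scalings, other filters, each replicate left out, and a replicate block. The share of ribosomal protein counts was compared with an exact permutation test. A further alternative, removal of each library's lowess trend on exon length, was chosen after seeing the data.

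The rule for named genes, fixed before the data were examined, took the 4 Y-box genes, the 8 largest positive and 8 largest negative log2 fold changes among called genes with non-overlapping groups and at least 5 CPM in the higher group, the 3 called members with the largest absolute change of each list with at least 3 called members or past its test, the most abundant member of any other list, and the 5 most abundant genes. The text gives part of them, and 1 gene that the rule takes is not reported here. Figures were drawn with matplotlib.

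On simulated data with the means, library sizes and 13944 genes of this comparison, edgeR called 91% of the genes changed 2-fold and 62% of those changed 1.5-fold, and 5.49% of its calls were unchanged genes. With a simulated length trend 317 unchanged genes were called before its removal and 7 after. The simulated genes varied independently, and far fewer changed than were called here. The simulated trend was 1 slope shared by both mutant libraries and absent in wild type. In the data replicates of a group also differ in trend, so these rates do not measure the error here. Library totals of 24717311 to 33009708 counts leave counting error small for genes above a few CPM, and the number of libraries limits the precision.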

Results

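Total RNA from whole young adult Caenorhabditis elegans was sequenced in 4 libraries. A set of 2 libraries came from N2, the standard wild-type strain, and the other 2 came from a strain carrying the alleles cey-1(rrr12) and cey-4(ok858), called the cey-1 cey-4 mutant here. Both genes encode Y-box proteins, RNA-binding proteins with a cold shock domain that coat mRNA. The RNA was taken from lysates that also served for ribosome profiling. Summed gene counts were 29773406 and 31311497 for wild-type replicates 1 and 2, and 33009708 and 24717311 for mutant replicates 1 and 2. The table listed 20182 genes, of which 2057 had no count in any library. Levels are given as TMM-scaled CPM, counts relative to the library total, as mean ± SD of 2 libraries, and log2 fold changes are mutant over wild type with the standard error implied by the test statistic.

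The first question was whether the mutated genes showed in the libraries that carry the strain's label. Transcripts of cey-4 (WBGene00000475) were counted 23072 and 23781 times in the wild-type libraries and 338 and 280 times in the mutant libraries. The level fell from 774 ± 17.4 to 10.7 ± 0.831 CPM, a log2 fold change of -6.18 ± 0.12 (edgeR quasi-likelihood test, adjusted p = 5.494e-10). Transcripts of cey-1 (WBGene00000472) had 4218 and 4042 counts in wild type against 723 and 609 in the mutant, and fell from 137 ± 10.1 to 23.1 ± 2.06 CPM (log2 fold change -2.57 ± 0.11, edgeR adjusted p = 1.326e-06). In the Ensembl annotation of assembly WBcel235, cey-1 spans positions 11039348 to 11041206 of the minus strand of chromosome II and cey-4 spans 10866946 to 10868703 of the minus strand of chromosome III. The build behind the deposited counts is not given in the sources used here. The related germline genes cey-2 and cey-3, intact in this strain, had log2 fold changes of -0.29 ± 0.11 and -0.23 ± 0.09, which did not pass (edgeR adjusted p = 0.0881 and 0.0874). As a list, the 4 Y-box genes were lower (camera adjusted p = 2.308e-30, adjusted p = 0.206 with an estimated correlation), with 2 members lower over all genes tested and 4 adjusted over the list alone. As 2 of its 4 members are the mutated genes, that outcome follows from the strain and is no separate finding. Because cey-1 overlaps srlf-15 and cey-4 touches oxi-1 on the other strand, and strand use in counting is not stated, a few of the remaining counts cannot be assigned with certainty. The same uncertainty holds for unc-22, unc-89, gon-1, pas-7, rrp-1, sod-3, vit-2, col-124 and ugt-59, each of which overlaps a gene on the opposite strand.

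**Figure D1:**
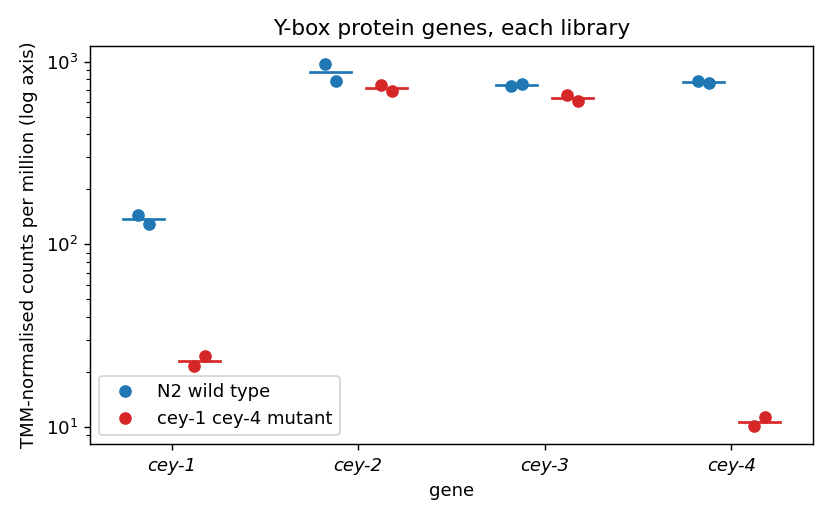
Level of the 4 Y-box protein genes in each library, in TMM-normalised CPM on a log axis. Points are libraries (2 per group, blue for N2 wild type and red for the cey-1 cey-4 mutant) and bars are group means. The mutant means are 23.1 CPM for cey-1 and 10.7 CPM for cey-4, against 137 and 774 CPM in wild type.

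The main comparison asked which transcripts differ in abundance between the mutant and wild type. Of 13944 genes tested, 1821 were higher and 1858 were lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Changes over 2-fold were made by 499 higher and 286 lower genes, and changes under 1.5-fold by 582 higher and 1020 lower genes. The median absolute log2 fold change of the called genes was 0.65. In each of the 3679 called genes both mutant libraries lay outside both wild-type libraries, which calling with 2 libraries per group all but requires. The same held for 64.04% of all tested genes, where chance gives 33.3% on average. Genes move together within a library, so a single share can lie far from that average. The gap does not by itself show an effect of the mutation. Leaving out a library moved the counts in either direction: without mutant replicate 1 there were 961 higher and 874 lower genes and without mutant replicate 2 there were 1038 and 447, against 2042 and 2307 without wild-type replicate 1 and 2005 and 1682 without wild-type replicate 2.

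Fold changes also followed transcript length, and the libraries of a single group did so as well. Among 7942 protein-coding genes of at least moderate abundance, the median log2 fold change was -0.24 for summed exon lengths up to 1 kb, -0.08 from 1 to 2 kb, 0.05 from 2 to 4 kb and 0.18 over 4 kb. Across these genes, which are not independent replicates, the Spearman correlation of length with the difference was -0.33 for wild-type replicate 2 minus 1 and 0.39 for mutant replicate 2 minus 1. It was 0.23 to 0.49 for the 4 differences of a mutant minus a wild-type library. A fit with each library's length trend removed, chosen after seeing the data, gave 1823 higher and 1524 lower genes, of which 2979 were among the 3679. Its values stand below beside the lists whose medians or calls it moved most.

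**Figure D2:**
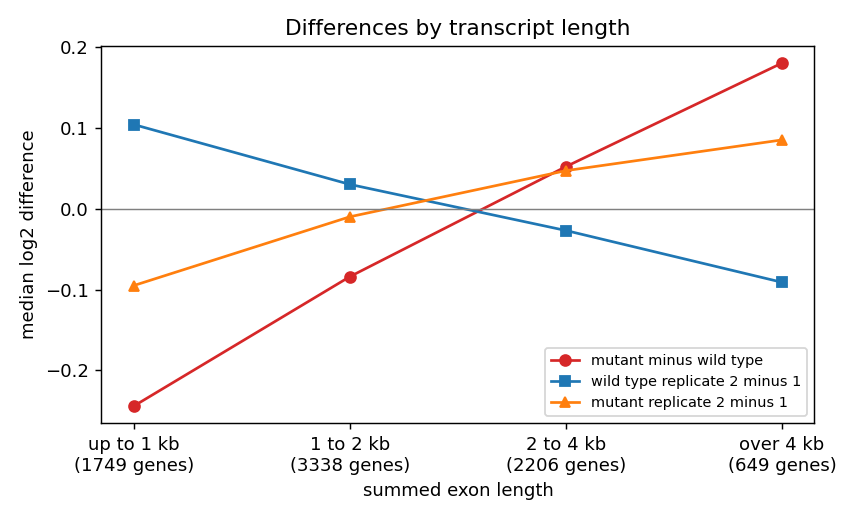
Median log2 difference of 7942 protein-coding genes by class of summed exon length. Red circles are the mutant over wild-type fold changes, blue squares wild-type replicate 2 minus replicate 1, and orange triangles mutant replicate 2 minus replicate 1. The red medians run from -0.24 for the shortest class to 0.18 for the longest, and each pair of replicates also shows a slope.

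The genes with the largest rise among those of at least 5 CPM included T05A12.4 (WBGene00020235, chromosome IV, 6887948 to 6897783), which went from 32 ± 1.73 to 117 ± 2.46 CPM (log2 fold change 1.88 ± 0.10, edgeR adjusted p = 6.14e-06). T10D4.6 rose from 19.9 to 63.4 CPM, a log2 fold change of 1.67 ± 0.11. The snRNA-activating complex subunit gene snpc-1.3 rose from 1.26 ± 0.149 to 5.97 ± 0.232 CPM (2.25 ± 0.19), although it overlaps acl-6 on the opposite strand. The other 5 of the 8 largest rises had no symbol in the name table. WBGene00020164, WBGene00021055, WBGene00017035 and WBGene00010092 are annotated as pseudogenes, with log2 fold changes of 2.05, 2.03, 1.92 and 1.76, and WBGene00021663, with 2.90, has no position in the annotation used here. Apart from the mutated genes, the largest falls among genes of at least 5 CPM in the higher group were those of the F-box gene fbxa-192 (WBGene00010212, chromosome V, 17640672 to 17650527), from 7.96 ± 0.512 to 0.918 ± 0.241 CPM (log2 fold change -3.14 ± 0.21), scl-6 (-2.21 ± 0.21) and T03D3.5 (-2.09 ± 0.14). Y62H9A.4 fell from 48.1 to 12.7 CPM (-1.92 ± 0.13), followed by T28A11.2 (-1.82) and C09B8.4 (-1.76). Among the most abundant genes of the table, the yolk protein genes vit-6 and vit-1 and the collagen gene col-124 did not pass, with log2 fold changes of 0.39 ± 0.17, 0.49 ± 0.20 and -0.20 ± 0.12.

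The list of sperm genes was higher at the preset correlation. Of 60 tested genes of sperm and sperm development other than the major sperm proteins, 41 were higher and 0 lower, 45 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 0.67 (camera adjusted p = 3.732e-18, adjusted p = 0.436 with an estimated correlation). Examples were nspd-6, from 3.46 ± 0.269 to 10 ± 0.18 CPM (log2 fold change 1.54 ± 0.15), and ssp-9 (1.85 ± 0.37), which was not called without mutant replicate 1 (1.81). Removing the length trend left 47 higher members and a median of 0.76. The major sperm proteins, the cytoskeletal proteins that drive sperm crawling, had 4 of 18 members higher and 0 lower, 4 and 0 adjusted over the list alone, with a median of 0.67 (camera adjusted p = 0.01979, adjusted p = 0.721 with an estimated correlation). Their genes are near-identical copies whose reads can be split between members, and the list did not pass without wild-type replicate 1 (adjusted p = 0.066), without mutant replicate 1 (0.157) or with a mean of at least 50 counts required (0.0868). Removal of the length trend gave 8 higher members and a median of 0.87. Of the 38 genes of Argonaute and RNA interference factors, 5 were higher and 5 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.3629), and the list's median of 0.06 became -0.03 with the length trend removed. The largest changes in it were rises of wago-10 (1.29 ± 0.17), alg-4 (0.96 ± 0.09) and alg-3 (0.78 ± 0.10), and alg-3 and alg-4 encode Argonautes of the male germline.

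The lists of mitochondrial ribosomal proteins and of translation factors were lower at the preset correlation. Of 69 mitochondrial ribosomal protein genes, 43 were lower and 0 higher, 56 lower adjusted over the list alone, with a median log2 fold change of -0.37 (camera adjusted p = 3.392e-13, adjusted p = 0.676 with an estimated correlation). The level of mrps-10 fell from 23.2 ± 0.0588 to 12.62 ± 0.466 CPM (-0.88 ± 0.11), that of mrps-17 from 75.3 to 41.5 CPM (-0.86 ± 0.11) and that of mrpl-35 from 11.4 to 6.27 CPM (-0.87 ± 0.16, overlapping hmit-1.3 on the opposite strand). After removal of the length trend 27 were lower, with a median of -0.23. Of 44 translation initiation and elongation factor genes, 18 were lower and 1 higher, the same numbers adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0004495, adjusted p = 0.676 with an estimated correlation). The eIF4E gene ife-4 (-0.76 ± 0.15), eif-1 (-0.53 ± 0.11) and eef-1B.1 (-0.50 ± 0.11) were lower, none of them called without mutant replicate 2 (-0.65, -0.37 and -0.35). The list's median was -0.23 with the length trend removed, and it still passed. The most abundant factor, eef-1A.1, had a log2 fold change of -0.33 ± 0.11 (edgeR adjusted p = 0.04465) and missed the threshold with DESeq2 size factors (-0.31), library size alone (-0.30), a mean of at least 50 counts (-0.29) and limma on the deposited values (-0.30), and without wild-type replicate 2 (-0.25) or either mutant replicate (-0.33 and -0.28).

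The 83 cytoplasmic ribosomal protein genes had 11 lower members and 1 higher, 8 and 1 adjusted over the list alone, with a median log2 fold change of -0.15 (camera adjusted p = 0.01122, adjusted p = 0.721 with an estimated correlation). Of all tested protein-coding genes 13.8% were lower and 12.5% higher, so 11 of 83 is no excess of lower members. The list did not pass without wild-type replicate 2 (median -0.04, adjusted p = 0.567) or without mutant replicate 2 (-0.09, adjusted p = 0.0672), and with the length trend removed its median was 0.02 (adjusted p = 0.742). Among its members rpl-2 fell from 767 ± 101 to 525 ± 43 CPM (-0.55 ± 0.11, overlapping dhcr-7 on the opposite strand and not called without mutant replicate 2, -0.44) and rpl-42, weakly counted, rose from 2.45 to 4.87 CPM (0.997 ± 0.18). The fall of rpl-6 (-0.50 ± 0.14) was not called with the length trend removed (-0.32) or without either mutant replicate (-0.61 and -0.36). As a share of all counts these 83 genes took 7.87% and 9.29% in wild type and 7.90% and 7.67% in the mutant. The means of 8.58 ± 1.01 and 7.79 ± 0.164% differed by -0.793 points, less than the wild-type spread, and the exact two-sided permutation test on 2 against 2 libraries gave p = 0.667, where the smallest p it allows is 0.333. The difference was -0.080 points without wild-type replicate 2 and -1.51 without wild-type replicate 1. Of 25 genes of ribosome biogenesis and the nucleolus, 5 were lower and 1 higher (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.1223). In it rpoa-12 and rrp-1 had log2 fold changes of -0.49 and -0.42 (not called without mutant replicate 2, -0.45 and -0.31, and rpoa-12 not with the length trend removed, -0.29) and gar-1 of 0.82 (not called without mutant replicate 1, 0.73). In this species gar-1 encodes a muscarinic acetylcholine receptor, not a nucleolar protein, so the higher member of the list as fixed is not a ribosome biogenesis gene. The list had 8 lower members and passed with the length trend removed (median -0.15, camera adjusted p = 0.0207). As counted, camera with an estimated correlation gave an adjusted p of 0.676. Without wild-type replicate 2, which leaves a lone wild-type library, the list passed as counted with a median of -0.099.

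Proteasome genes were lower as a list, and oxidative phosphorylation genes as counted but not with the length trend removed. Of 33 proteasome genes 20 were lower and 1 higher, 24 and 1 adjusted over the list alone, with a median log2 fold change of -0.34 (camera adjusted p = 2.682e-06, adjusted p = 0.676 with an estimated correlation). The core particle genes pas-7 and pas-5 fell by 0.57 and 0.53 on the log2 scale, calls that were not made without mutant replicate 2 (-0.43 and -0.46). The member that rose was rpn-6.2, from 24 ± 1.26 to 34.2 ± 0.29 CPM (0.51 ± 0.10). Removing the length trend left 18 members lower (median -0.29). Of 44 nuclear oxidative phosphorylation genes 12 were lower and 0 higher, 13 and 1 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.00836, adjusted p = 0.721 with an estimated correlation). They included cox-14 (-0.66 ± 0.10), cox-6C (-0.56 ± 0.09) and the cytochrome c gene cyc-2.1 (-0.67 ± 0.13, not called without mutant replicate 2, -0.49). This list did not pass with the length trend removed (median -0.05, adjusted p = 0.189).

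Lipid genes fell more often than they rose. Of 56 genes of fat and lipid metabolism 24 were lower and 8 higher, 25 and 11 adjusted over the list alone, with a median log2 fold change of -0.25 (camera adjusted p = 0.004921, adjusted p = 0.676 with an estimated correlation). The fatty acid binding protein genes lbp-2 and lbp-5 fell from 283 ± 64.1 to 96 ± 12.1 CPM (-1.56 ± 0.15) and from 37.9 to 20.2 CPM (-0.90 ± 0.11), and the lysosomal lipase gene lipl-4 rose from 0.263 to 0.966 CPM (1.89 ± 0.41, not called without mutant replicate 1, 1.54). The numbers were again 24 lower and 8 higher with the length trend removed. Of 161 xenobiotic detoxification genes 33 were lower and 9 higher, the same adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.03811, adjusted p = 0.721 with an estimated correlation). This list did not pass without wild-type replicate 2 (adjusted p = 0.0829), without mutant replicate 2 (0.0793) or without a filter on low counts (0.0521). Its members with the largest changes, ugt-18, ugt-15 and ugt-59, had group means below 1 CPM. Of 26 heat shock and unfolded protein response genes 6 were lower and 0 higher, the same adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0422, adjusted p = 0.676 with an estimated correlation). Small heat shock protein genes hsp-43 (-0.81 ± 0.12) and sip-1 (-0.46 ± 0.09, not called without either mutant replicate, -0.50 and -0.38) were among them. The list missed the threshold without wild-type replicate 1 (0.0845), without either mutant replicate (0.078 and 0.145), with library size alone (0.0514), and with either other filter (0.0644 and 0.0755).

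**Figure D3:**
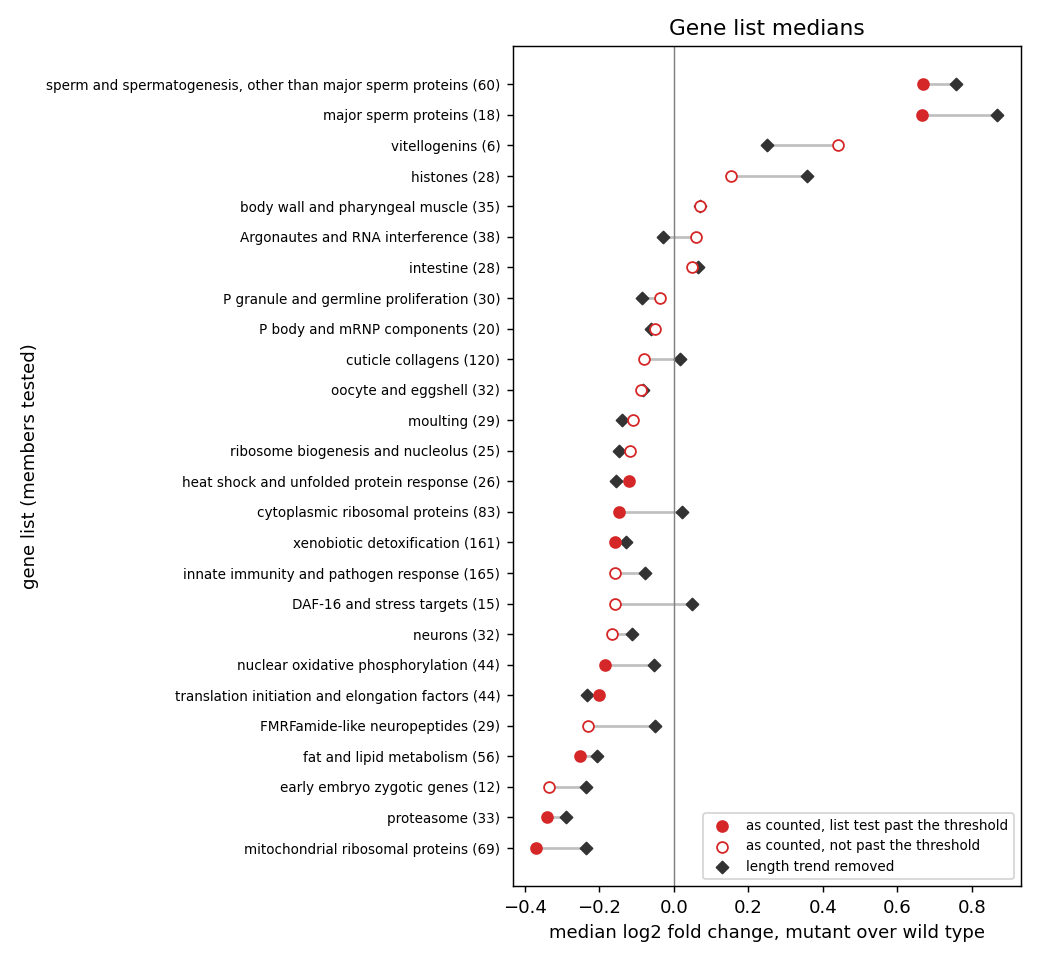
Median log2 fold change of each fixed gene list with tested members, mutant over wild type, leaving out the Y-box list. Red circles are the values as counted, filled where the list test passed, and dark diamonds, hidden where they coincide, are the values with the length trend removed. The sperm list lies at 0.67 and moves to 0.76, and the cytoplasmic ribosomal protein list lies at -0.15 and moves to 0.02.

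The other lists did not pass as counted. Of 32 oocyte and eggshell genes 4 were lower and 0 higher, 3 and 0 adjusted over the list alone (median -0.09, camera adjusted p = 0.08508). Among the lower genes were perm-2, from 218 ± 28 to 112.1 ± 2.91 CPM (-0.96 ± 0.11), cpg-3 (-0.84 ± 0.10) and egg-1 (-0.34 ± 0.09, not called without either mutant replicate, -0.28 and -0.36). Each of these 3 overlaps a gene on the opposite strand. The list had 8 lower and 1 higher and passed with the length trend removed (median -0.08, camera adjusted p = 0.0207). As counted, camera with an estimated correlation gave an adjusted p of 0.721. The list passed as counted without wild-type replicate 2 (median -0.136) and without mutant replicate 2 (-0.123), fits that leave a lone library in a group. Of 6 vitellogenin genes, which encode yolk, 3 were higher and 0 lower, 5 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.08926). These 3 were vit-2 (0.72 ± 0.24), vit-5 (0.51 ± 0.13) and vit-4 (0.39 ± 0.12), near-identical in part, and none was called with the length trend removed (0.54, 0.33 and 0.20), without mutant replicate 1 (0.81, 0.50 and 0.46) or without mutant replicate 2 (0.66, 0.56 and 0.36). Calls were also lost for vit-2 with DESeq2 size factors (0.73), the DESeq2 test (0.73) and a mean of at least 50 counts (0.74), and for vit-4 without wild-type replicate 2 (0.24). The list's median was 0.25 with the length trend removed, with 0 members higher and 1 lower (adjusted p = 0.4444). Without wild-type replicate 1, which leaves a lone wild-type library, the list passed as counted with a median of 0.71. Wild-type replicate 2 minus 1 was itself -0.507 for this list as counted. With an estimated correlation, 0.97 for this list, the list as counted did not pass (camera adjusted p = 0.721). Of 28 histone genes 8 were higher and 2 lower, 9 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.133). The H3 gene his-70 rose from 3.25 to 7.67 CPM (1.25 ± 0.18). As many as 14 histone genes were higher and the list passed with the length trend removed (median 0.36, camera adjusted p = 0.0004917). As counted, camera with an estimated correlation gave an adjusted p of 0.721. Without wild-type replicate 2, which leaves a lone wild-type library, the list passed as counted with a median of 0.175. Histone genes occur in near-identical copies.

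Among tissue lists, 9 of 35 muscle entries were higher and 3 lower, 10 and 3 adjusted over the list alone (median 0.07, camera adjusted p = 0.08988). The gene pat-10 is in this list by both of its rows. The giant sarcomere genes unc-22 and unc-89 rose from 2161 ± 13.2 to 4051 ± 271 CPM (0.91 ± 0.10) and from 932 to 1626 CPM (0.80 ± 0.10), and their log2 fold changes were 0.47 and 0.35 with the length trend removed. The list passed with DESeq2 (adjusted p = 0.0328) and without wild-type replicate 2 (0.0293). The troponin gene tni-1 fell from 89.5 to 46.7 CPM (-0.94 ± 0.13). Of 28 intestine genes 5 were higher and 2 lower (camera adjusted p = 0.3889), with ifo-1 at 0.73, gon-1 at 0.67 and cpr-1 at -0.64. The list as fixed holds gon-1, which encodes an ADAMTS metalloprotease known from gonad and muscle and is no intestinal marker, and its value was 0.40 with the length trend removed. Of 32 neuron genes 2 were higher and 6 lower (camera adjusted p = 0.2697), and the proprotein convertase gene egl-3 fell from 77.6 to 43 CPM (-0.86 ± 0.12). Of 29 FMRFamide-like neuropeptide genes 1 was higher and 2 lower (camera adjusted p = 0.2697), with flp-17 at -0.81, and the list's median of -0.23 was -0.05 with the length trend removed. Adjusted over the list alone these 3 lists gave the same numbers. Of 120 cuticle collagen genes 13 were higher and 26 lower, 15 and 28 adjusted over the list alone (median -0.08, camera adjusted p = 0.08191), and col-95 fell from 9.9 to 3.16 CPM (-1.65 ± 0.18). This list passed with DESeq2 (adjusted p = 0.0434), without wild-type replicate 1 (0.00284) and without mutant replicate 1 (0.0234), and its median was 0.02 with the length trend removed. Of 29 moulting genes 3 were higher and 2 lower (camera adjusted p = 0.8226). Their median, -0.11, and mean, -0.01, were negative while the list test pointed up, and qua-1 and mlt-11 rose by 1.13 and 0.71 on the log2 scale.

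In the germline and RNA granule lists, 3 of 20 P body and mRNP genes were lower and 0 higher (camera adjusted p = 0.4413). The DEAD-box helicase gene cgh-1, an RNA-binding partner of Y-box proteins in germline granules, fell from 1272 ± 62.5 to 821 ± 21.8 CPM (-0.63 ± 0.09). The others were lsm-3 (-0.81 ± 0.13, overlapping mdt-9) and car-1 (-0.32 ± 0.09, not called without either mutant replicate, -0.37 and -0.24, or with a mean of at least 50 counts, -0.29). Of 30 P granule and germline proliferation genes 2 were higher and 0 lower (median -0.04, mean 0.001, test pointing down, camera adjusted p = 0.71), and the most abundant, glh-1, had a log2 fold change of 0.04 ± 0.11, which was -0.07 without wild-type replicate 2 and -0.04 with the length trend removed. The median of that list was then -0.09. Of 12 early embryonic genes 2 were higher and 4 lower (camera adjusted p = 0.244), with elt-1 at 0.94, and the median was -0.33 as counted and -0.23 with the length trend removed. Of 165 innate immunity genes 22 were higher and 38 lower, 23 and 41 adjusted over the list alone (camera adjusted p = 0.08508), and the lectin genes clec-33 (not called by DESeq2, 4.06) and clec-28, with 3.94 and 2.87, had group means below 1 CPM. The immunity list's median was -0.16 as counted and -0.08 with the length trend removed. It passed with a mean of at least 50 counts (adjusted p = 0.0213) and without mutant replicate 1 (0.0186). Of 15 DAF-16 and stress target genes 2 were higher and 5 lower (camera adjusted p = 0.3889), with dod-23 at 0.96 and the superoxide dismutase gene sod-3 at -1.03 (not called without mutant replicate 1, -0.83), and the list's median of -0.16 was 0.05 with the length trend removed. Adjusted over the list alone, the P body, P granule, early embryo and DAF-16 lists gave the same numbers, as did the moulting list. In all, 11 of 27 lists passed, 2 of them higher and 9 lower, the Y-box list included, and 0 passed with an estimated correlation (2 at an unadjusted p below 0.05), where the smallest adjusted p was 0.206.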

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

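The length-trend removal was chosen after seeing the data, the other settings before. Leaving out 1 replicate at a time gave 961 to 2042 higher genes, 447 to 2307 lower genes and 9 to 13 passing lists. The lowest counts came without a mutant replicate, where a lone library is assumed to vary like the other group (961 and 874 without mutant replicate 1, 1038 and 447 without mutant replicate 2). DESeq2 called 1411 and 1324 genes, and no filter gave 2201 and 1974. With an estimated correlation 0 lists passed and with fry 1, the Y-box list. Values of cey-4 ran from -6.23 to -6.09 and of cey-1 from -2.63 to -2.46 over the settings.

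Reversals were few, and their cause was not tested beyond the length trend itself. With the length trend removed, the list test turned for the cytoplasmic ribosomal proteins (median 0.023), the Argonautes (median -0.028) and the moulting genes (median -0.139, negative as counted too), and glh-1 was -0.038. The P granule list reversed in its test without wild-type replicate 1 (-0.019) and without mutant replicate 1 (0.011), in a range of medians from -0.064 to 0.011 with 1 replicate left out, and glh-1 without wild-type replicate 2 (-0.065), in a range from -0.065 to 0.171. Among named genes 111 of the comparisons with a setting lost a call and 8 gained one.

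Replicate numbers are shared by the groups but are not said to pair libraries. The replicate differences of the groups correlated at -0.073 across genes. With the replicate block 1792 genes were higher and 1727 lower, 3410 of them among the 3679, and 11 lists passed, 10 of them among the 11 as counted. With this block the heat shock list did not pass (adjusted p = 0.05177), the vitellogenin list did (median 0.471, adjusted p = 0.04067), and eef-1A.1 (-0.324) and car-1 (-0.322) were not called. cey-1 and cey-4 kept -2.57 and -6.18.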

Other observations

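The tests on gene families, chromosomes, neighbouring genes, the length trend, animal age and sperm RNA as a source of pseudogene counts were chosen after the results were seen, as was the form used of the genomic DNA test. The test of pseudogenes as a class was not among the results planned in advance. Among 121 families of genes sharing a symbol prefix, with at least 10 tested members, 26 passed the list test and 18 of these kept direction and call with the length trend removed; with an estimated correlation none did (camera, smallest adjusted p = 0.9224). The transthyretin-like ttr genes, secreted proteins of nematodes, had 33 of 51 members lower and 0 higher (median log2 fold change -0.67, camera adjusted p = 6.451e-14, median -0.47 with the trend removed). Short-chain dehydrogenase genes (dhs) had 14 of 29 lower and 1 higher (median -0.49), and saposin-like spp genes had 8 of 17 lower and 0 higher (median -0.50). Neprilysin-like nep genes had 12 of 21 higher and 0 lower (median 0.57), and acyltransferase oac genes 9 of 21 higher and 0 lower (median 0.49).

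Calls were unevenly spread over chromosomes. On the X chromosome 161 of 1899 tested genes were higher (8.48%, against 13.6% on the autosomes, odds ratio 0.586, Fisher's exact p = 9.398e-11, adjusted over 4 tests 1.88e-10) and 295 were lower (15.5% against 13.3%, odds ratio 1.2). With the length trend removed the odds ratios were 0.417 and 1.36. Genes are not independent replicates in such tests. Within 50 kb of cey-4, 6 of 12 tested genes were called and 4 of them over 2-fold (Fisher's exact p = 0.003408, adjusted over 2 tests 0.006816). Elsewhere 5.6% of tested genes were called over 2-fold, and 26.4% of all tested genes were called. The adjacent convergent gene oxi-1 (chromosome III, 10858284 to 10866946 in WBcel235) had a log2 fold change of -1.72, and fbxb-85, C44B9.2 and Y39A1C.1 had 2.25, 1.27 and -1.07. Because oxi-1 touches cey-4 and strand use is not stated, its value may not be independent of the mutated gene. The test near cey-4 counts oxi-1 and treats adjacent genes as separate trials, so its p may be too small. Within 50 kb of cey-1, 1 of 10 was called and 0 were over 2-fold.

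Annotated pseudogenes were higher in the mutant: 93 of 258 tested were higher and 7 lower, with a median log2 fold change of 0.42, against 12.5% and 13.8% of protein-coding genes (odds ratio of a higher call 3.95, 95% interval 3.02 to 5.16, Fisher's exact p = 1.031e-21). Genes are not independent replicates here, so the interval and p do not measure the spread between libraries. The skew was not particular to pseudogenes: of 351 tested IDs not in the annotation, 64 were higher and 6 lower (median 0.172). Genomic DNA carried over into the mutant libraries is argued against, since 1294 annotated chemoreceptor genes, mostly silent in whole worms, gained at most 0.011 times as much per kb as all 720 annotated pseudogenes in any of the 4 library pairs (10% trimmed means, 0.0798 to 0.0885 CPM per kb for pseudogenes). Their summed level was 72.3 and 75.1 CPM in wild type and 73.1 and 76.1 CPM in the mutant, and the form of this test first planned, on medians, has no value because the median gain of all pseudogenes was 0. Low expression alone is argued against by the highest median of 1000 expression-matched coding sets, 0.177. More sperm RNA in the mutant libraries stays open, because the test made of it cannot decide. Among genes with a mean log2 CPM above 1, called or not, 21 pseudogenes (20.2%) lay above the sperm genes' 90th percentile of 1.16. The share of sperm genes above it, 5 of 50 (10%), is set by that cut, so the comparison (Fisher's exact p = 0.1672) is not informative. The share above a cut also grows with imprecision, and median standard errors were 0.183 for these pseudogenes and 0.141 for these sperm genes. Median log2 fold changes were 0.288 for these pseudogenes and 0.587 for these sperm genes. An earlier form of the test, set aside, counted called pseudogenes alone. Reads shared with parent genes and changed decay of pseudogene RNA were not tested.

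The lower lists split when the trend on length was removed. Median exon length was 542 bases for cytoplasmic ribosomal proteins, 763 for mitochondrial ribosomal proteins and 932 for nuclear oxidative phosphorylation. It was 1235 for the proteasome, which is not a short-gene list. For cytoplasmic ribosomal proteins the call ended because the median went from -0.148, with library pairs between -0.285 and -0.008, to 0.023, with pairs between -0.055 and 0.082, so a length trend that differs between libraries may account for that fall. Nuclear oxidative phosphorylation also lost its call, with a median of -0.183 as counted and -0.053 after removal. For mitochondrial ribosomal proteins the corrected median was -0.234, with all 4 library pairs between -0.28 and -0.193, which argues against the trend as the whole cause there. After removal, coding genes up to 1 kb still had a median of -0.079, against -0.026 over 4 kb. For the proteasome the corrected median was -0.288, between -0.318 and -0.204. Coding genes of 1 to 2 kb had a median of -0.084 as counted and -0.051 after removal, so this list had little trend to lose. Whether the trend comes from library handling alone or in part from the mutation stays open, because it differs both between replicates of a group and between the groups. An effect of the lost Y-box proteins on these mRNAs stays among the open explanations.

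The rise of sperm genes was weighed against the make-up of the cultures. Males among the mutant animals are not excluded. Summed counts of 7 male-neuron markers had log2 ratios from -0.731 to 0.16 over the 4 library pairs, each below the sperm median of 0.67. With only 24 to 51 counts per library, these ratios are too imprecise to exclude males. Mutant animals younger at harvest cannot be told apart from an effect of the mutation, because both outcomes named for that test were met. Oocyte and eggshell genes were lower with the length trend removed (median -0.082, library pairs from -0.261 to 0.003) at the preset correlation. As counted, camera with an estimated correlation gave that list an adjusted p of 0.721. The vitellogenin median was above 0 in each library pair, by 0.037 and 0.056 against wild-type replicate 1 and 0.505 and 0.432 against replicate 2. Wild-type replicate 2 minus 1 was itself -0.507 for vitellogenins as counted, so the size of this outcome rests largely on 1 wild-type library. An earlier form of that test, on vitellogenins as counted, had spoken against younger animals (lowest library pair 0.145) and was set aside because vitellogenins are long and the length trend raises them. An effect of the mutation on sperm genes stays among the open explanations, as untested.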
